A study of Homo sapiens with 56 samples.

How the data were processed

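The series holds RNA sequencing of primary human bronchial epithelial cells from 4 donors, with 2 wells per donor in each of 7 groups. Per the labels, cells grew on 12 mm transwells for at least 28 days, were given 10 puffs of 3 s at 2 L/min with rests of 10 min, and were lysed after the last puff. Each puff had earlier been found to deposit 49.5 µg/cm2 (± 2.75), per the labels. The labels give a 3.7 V battery with a ceramic coil for the distillates and another tank for juices and control, and a new mouthpiece for the Stiiizy disposable.

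The deposited file holds raw counts per gene, not normalized, for 56 libraries. Per the labels, reads were paired-end and mapped to GRCh38 with ERCC spike-in sequences, and per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b and Subread 1.5.2. Neither the annotation release nor the strand setting is stated. Of 58143 rows, 92 are ERCC spike-ins and 58051 are genes. Symbols matched 56948 gene identifiers, and the 1103 unmatched ones held 0.099% of counts. Coordinates come from an annotation of GRCh38 in which the identifiers matched. XIST, TSIX and genes on chromosome Y, 508 rows in all, were removed before any test to protect donors, leaving 57543 genes. Every column matched a sample. Total counts per library ran from 14917411 to 26132525, and these limit the precision of low-count genes.

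Counts of the 2 wells of a donor and product were summed, giving 28 sums, because the donor is the unit of replication. EdgeR 4.0.16 in R 4.3.3 filtered genes by filterByExpr, which left 21664, scaled by TMM and fitted a quasi-likelihood model with a term for group and a term for donor on all 28 sums (18 residual degrees of freedom, common biological coefficient of variation 0.0819). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were each of the 6 products against PG/VG control, the mean of the 4 distillates against the mean of both juices, Strawberry against Green Apple juice, and any difference among the 4 distillates. The fit was also tried on simulated data.

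Donor numbers pair the samples by design, since each donor received every product. This was checked on deviations from group means, where all 84 correlations between sums of the same donor were above 0.1 (lowest 0.406, median 0.565). The highest between different donors was 0.035. Deviations cancel within each group, so positive correlations of the same donor push those between different donors to negative values. The value of 0.035 is therefore not separate evidence. The 28 pairs of wells differed by more than sampling noise, with chi-square per degree of freedom of 1.98 to 33.5.

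The 29 gene lists were fixed before the data were examined: NRF2 targets, heat shock proteins, ATF4 integrated stress response, ER unfolded protein response, metallothioneins and metal response, AHR targets, NF-kB and epithelial cytokines, interferon response, immediate early genes, EGFR ligands and ERK feedback, cholesterol synthesis, PPAR and lipid handling, hypoxia response, p53 targets, proliferation, mitochondrially encoded genes, ciliated cell markers, multiciliogenesis markers, secretory and goblet cell markers, basal cell markers, squamous markers, rare epithelial cell markers, markers of non-epithelial cells, cannabinoid and TRP receptors, xenobiotic and aldehyde metabolism, airway ion transport, nuclear-retained RNAs, circadian clock output, glucocorticoid response. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, in the 6 products and in distillates against juices, and p was adjusted over the 203 list tests. Camera was repeated with an estimated correlation, and fry was run as a second test. Each list also has a count of members called with p adjusted over the list alone. Some lists share members, so their results are not independent. The immediate early genes include IER3 of the EGFR list, ATF3 of the ATF4 list and DUSP1 of the glucocorticoid list. GDF15 is in the ATF4 and p53 lists.

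Named genes follow a rule written before the data were examined. Among genes with adjusted p under 0.05, a mean of at least 1 CPM, an approved-style symbol and the same sign in all 4 donors, the 10 largest rises and 10 largest falls were taken per product and for distillates against juices, 5 and 5 for Strawberry against Green Apple, the 10 smallest p among distillates, and up to 4 called members per list with the smallest adjusted p. Not every gene that the rule picks is printed. Donor signs came from log2 ratios with a pseudocount of 0.5 CPM. Library measures were compared between distillates and juices by an exact 2-sided permutation test that rearranges labels within donors.

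Alternatives were DESeq2 size factors in edgeR, total counts, DESeq2 1.42.0, no filter, at least 1 CPM in 8 sums, no donor term, wells as separate libraries, well 1 or well 2 alone, only the groups compared, an estimated correlation for lists, leaving out each donor, and split controls for shared calls. ERCC size factors and protein-coding genes only were added after seeing the data. Shared calls were compared with 100 simulations of unchanged groups against the same controls. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.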

Results

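RNA was sequenced from primary human bronchial epithelial cells (HBECs), cells of the airway lining that had grown at an air–liquid interface for at least 28 days. Cells from 4 donors received 10 puffs of aerosol from 1 of 6 commercial Δ8-THC products or from PG/VG control, a carrier of 40% propylene glycol and 60% vegetable glycerin. The 4 distillate products were the Palmetto cartridge, the Not Ya Son's Weed cartridge, the Palmetto disposable and the Stiiizy disposable. The other products were Serene Tree Strawberry juice and Serene Tree Green Apple juice. Each of the 7 groups had 2 wells per donor, giving 8 libraries per group and 56 in all, and the wells of a donor were summed for testing (n = 4 donors per group). The total count per library ran from 14917411 to 26132525, with a median of 19056092. Distillates were aerosolized with another device than the juices and the control, so the device and the kind of product were not separable, and the series holds no culture without aerosol.

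The libraries of distillates and juices differed in composition. Mitochondrially encoded RNA held 4.21% of counts with the distillates and 6.28% with the juices, against 6.83% ± 1.13 (SD, n = 4) in the control. MALAT1 and NEAT1, long RNAs that stay in the nucleus, together held 0.495% with distillates and 0.0679% with juices, against 0.0879% ± 0.0103 in the control. A mean of 28120 genes had at least 1 count in the distillate libraries and 25660 in the juice libraries. The 10 highest genes took 5.82% and 7.14%, the 100 highest 19.6% and 21.4%, and protein-coding genes 96.3% and 97.4%. For each of these 6 measures the direction was the same in 4 of 4 donors (exact permutation p = 2.0e-05, adjusted p = 3.0e-05 each, 2-sided, the smallest that the 50625 within-donor rearrangements allow, over 9 measures tested). ERCC spike-in RNA held 1.65% with distillates and 1.22% with juices (exact permutation p = 0.0091, adjusted p = 0.012), against 1.41% ± 0.244 in the control. The Palmetto cartridge had a lower mean than the other distillates, 1.19% ± 0.211, under the control and the 1.30% ± 0.295 of Green Apple juice. Total counts averaged 18520000 and 20250000 (exact permutation p = 0.023, adjusted p = 0.023), and counts in the genes used differed likewise (exact permutation p = 0.018, adjusted p = 0.020). These differences also went the same way in 4 of 4 donors. All these p-values come from rearranging the 6 product labels within each donor, so they do not measure the spread between products of a kind.

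**Figure D1:**
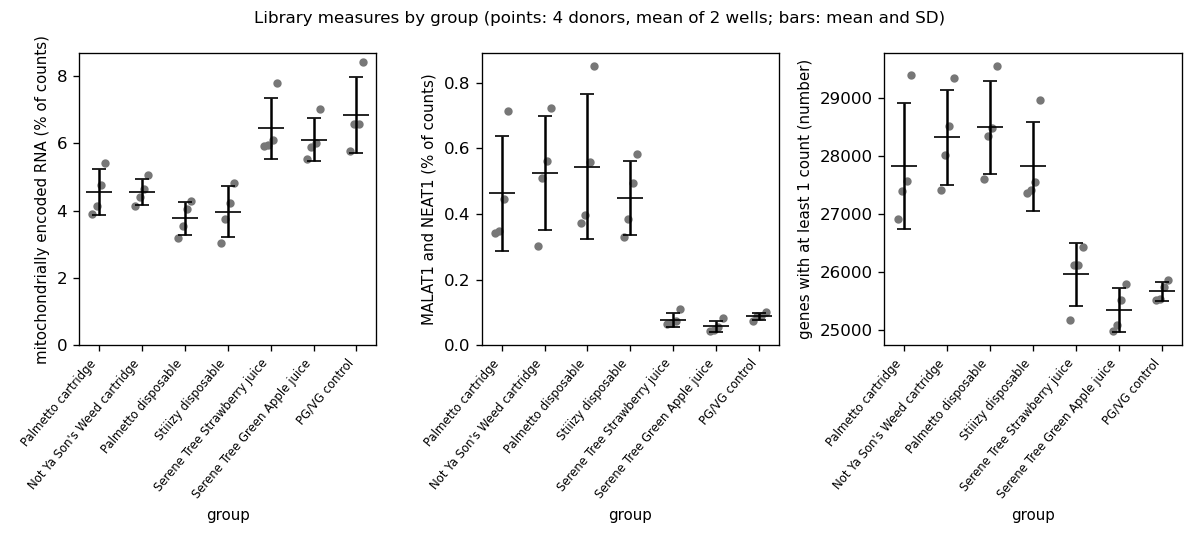
Share of counts from mitochondrially encoded RNA (%), share from MALAT1 and NEAT1 (%) and number of genes with at least 1 count, for the 7 groups. Points are the 4 donors (mean of 2 wells), horizontal lines the mean and bars the SD; distillates lie apart from juices and control in each panel.

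To characterize the effects of the products, each was compared with PG/VG control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the Palmetto cartridge, 11706 of 21664 genes passed an adjusted p of 0.05, 6195 of them higher and 5511 lower, and 2512 rose and 149 fell by at least 2-fold. The Not Ya Son's Weed cartridge gave 11851 called genes (6110 higher, 5741 lower), of which 2618 rose and 145 fell at least 2-fold. For the Palmetto disposable the count was 11143 (5636 higher, 5507 lower), with 2420 rises and 111 falls of at least 2-fold. For the Stiiizy disposable it was 10968 (5646 higher, 5322 lower), with 2257 and 137. Strawberry juice gave 1370 called genes (868 higher, 502 lower) and Green Apple juice 477 (348 higher, 129 lower). The split between higher and lower genes depended on the scaling. In the order Palmetto cartridge, Not Ya Son's Weed cartridge, Palmetto disposable and Stiiizy disposable, 52.9, 51.6, 50.6 and 51.5% of the called genes were higher with TMM factors and 96.4, 49.6, 28.7 and 17.3% with size factors from the ERCC spike-ins, and total counts gave 65.1% for the Palmetto cartridge. The juices' share was 63.4% for Strawberry and 73% for Green Apple with TMM, and 99.5% and 90.1% with ERCC. The ERCC factors shifted the median log2 change of all genes to 0.39, -0.07, -0.24 and -0.40 for the distillates in that order, 0.33 for Strawberry and 0.095 for Green Apple, and total counts shifted it to 0.14 for the Palmetto cartridge and 0.10 for the Not Ya Son's Weed cartridge. Changes reported with TMM are relative to the bulk of genes in each library.

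**Figure D2:**
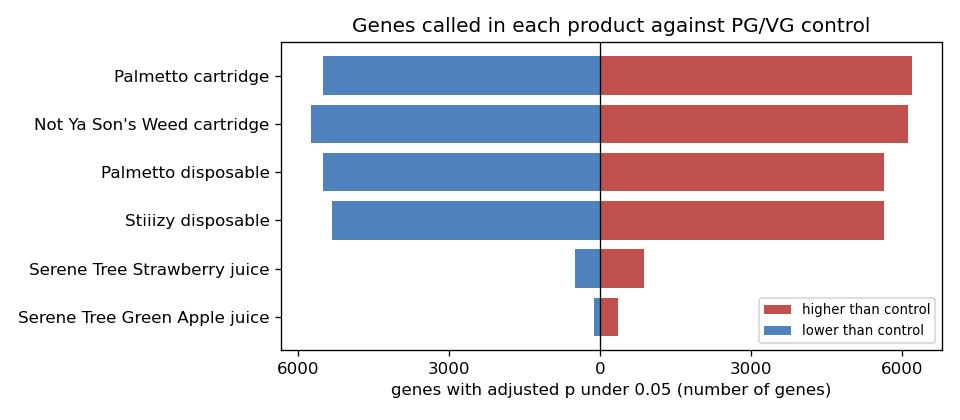
Number of genes with an adjusted p under 0.05 in each of the 6 products against PG/VG control, higher genes to the right and lower genes to the left of 0. The distillates have 10968 to 11851 called genes, Strawberry juice 1370 and Green Apple juice 477.

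Changes are given below as log2 fold changes ± SE and levels as mean CPM (scaled counts) ± SD over 4 donors. The 10 largest rises with the Palmetto cartridge were 7.35 ± 0.27 for NR4A1AS, 5.74 ± 0.19 for NR4A1, 5.72 ± 0.40 for IL6, 5.60 ± 0.21 for FOSB and 5.38 ± 0.12 for FOS. Then came 5.24 ± 0.16 for RASD1, 4.89 ± 0.27 for MIR3189, 4.88 ± 0.14 for DUSP2, 4.61 ± 0.39 for C11orf96 and 4.37 ± 0.44 for MIR616. FOS (ENSG00000170345; GRCh38 chromosome 14, 75278826 to 75282230), an immediate early transcription factor gene, stood at 1401 ± 136 CPM against 33.9 ± 6.23 CPM in the control (adjusted p = 5.8e-24). NR4A1 (GRCh38 chromosome 12, 52022832 to 52059507) was at 926 ± 446 CPM against 16.1 ± 2.35 CPM. The 10 largest falls were -2.45 ± 0.18 for BACH2, -2.31 ± 0.21 for MT-TG, -2.16 ± 0.18 for MT-TW, -1.99 ± 0.12 for MT-TL2 and -1.91 ± 0.20 for MT-TH. These were followed by -1.75 ± 0.09 for MT-TC, -1.74 ± 0.21 for CHAC1, -1.74 ± 0.19 for FAM131B, -1.72 ± 0.21 for NKX1-2 and -1.69 ± 0.17 for MT-TS2. BACH2 (GRCh38 chromosome 6, 89926528 to 90296843) went to 1.24 ± 0.258 CPM against 6.79 ± 0.993 CPM. Genes whose symbols begin with MT-T encode mitochondrial transfer RNAs. Whether their counts come from mature transfer RNAs or from longer mitochondrial transcripts was not tested.

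With the Not Ya Son's Weed cartridge the 10 largest rises were 6.80 ± 0.28 for NR4A1AS, 5.99 ± 0.34 for C11orf96, 5.88 ± 0.22 for FOSB, 5.80 ± 0.16 for RASD1 and 5.80 ± 0.39 for IL6. The next were 5.78 ± 0.19 for NR4A1, 5.42 ± 0.12 for FOS, 5.26 ± 0.14 for DUSP2, 5.21 ± 0.27 for ARC and 5.11 ± 0.27 for MIR3189. Its largest falls were -2.90 ± 0.19 for BACH2, -2.17 ± 0.12 for MT-TL2, -2.13 ± 0.17 for MT-TW, -1.98 ± 0.20 for MT-TH and -1.93 ± 0.20 for MT-TG. After them came -1.90 ± 0.17 for MT-TS2, -1.63 ± 0.09 for MT-TN, -1.57 ± 0.09 for TMEM97, -1.56 ± 0.16 for CDH6 and -1.56 ± 0.08 for MT-TC. FOS reached 1444 ± 99.5 CPM against 33.9 ± 6.23 CPM (adjusted p = 3.2e-24). For the Palmetto disposable the 10 largest rises were 7.17 ± 0.28 for NR4A1AS, 6.86 ± 0.33 for C11orf96, 6.45 ± 0.19 for NR4A1, 6.34 ± 0.22 for FOSB and 6.31 ± 0.16 for RASD1. Next in size were 5.95 ± 0.13 for FOS, 5.91 ± 0.25 for MIR3189, 5.86 ± 0.26 for ARC, 5.84 ± 0.39 for IL6 and 5.67 ± 0.38 for MIR616. This product's largest falls were -3.18 ± 0.19 for MT-TW, -3.15 ± 0.14 for MT-TL2, -3.09 ± 0.23 for MT-TG, -2.86 ± 0.19 for MT-TS2 and -2.82 ± 0.22 for MT-TH. Then came -2.01 ± 0.19 for MT-TF, -1.97 ± 0.09 for MT-TN, -1.83 ± 0.09 for MT-TC, -1.76 ± 0.11 for MT-TE and -1.70 ± 0.07 for MT-TY. Its FOS level was 2073 ± 184 CPM against 33.9 ± 6.23 CPM (adjusted p = 4.6e-25). For the Stiiizy disposable the leading rises were 7.19 ± 0.28 for NR4A1AS, 6.31 ± 0.19 for NR4A1, 6.28 ± 0.34 for C11orf96, 6.20 ± 0.22 for FOSB and 6.00 ± 0.16 for RASD1. These were followed by 5.93 ± 0.13 for FOS, 5.76 ± 0.27 for ARC, 5.68 ± 0.26 for MIR3189, 5.45 ± 0.14 for DUSP2 and 5.43 ± 0.39 for MIR616. Its leading falls were -3.01 ± 0.34 for CYP26A1, -2.63 ± 0.22 for MT-TG, -2.52 ± 0.13 for MT-TL2, -2.45 ± 0.18 for MT-TW and -2.45 ± 0.21 for MT-TH. The next were -2.28 ± 0.18 for MT-TS2, -2.13 ± 0.17 for BACH2, -2.11 ± 0.20 for MT-TF, -1.88 ± 0.09 for MT-TN and -1.75 ± 0.13 for PPP1R16B. CYP26A1, a retinoic acid hydroxylase gene, was at 11.03 ± 4.48 CPM against 93.02 ± 63.2 CPM (adjusted p = 3.6e-08).

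Some of these features share sequence or position with others, and the counting is not stated to use strand, so their own levels are uncertain. NR4A1AS lies antisense to NR4A1, MIR3189 lies within GDF15 and MIR616 within DDIT3, MT-TC and MT-TY are neighbours on the same strand, and IL6 overlaps an antisense gene. KRT16P2 is a pseudogene of the KRT16 family and TRIM16L a copy of TRIM16. ATF7-NPFF spans other genes, ESCO2 lies beside PBK, and FOSB beside ERCC1.

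The 29 gene lists fixed in advance were tested with limma's camera, which compares a list with all other genes. Values for the 4 distillates are given in the order Palmetto cartridge, Not Ya Son's Weed cartridge, Palmetto disposable and Stiiizy disposable. Of the list of immediate early genes, 22, 24, 24 and 24 of the 24 tested members rose and 0 fell, or 23, 24, 24 and 24 and 0 adjusted over the list alone. Median log2 changes were 2.93, 3.01, 3.59 and 3.38. Their camera adjusted p = 6.1e-30 to 3.4e-24. With an estimated correlation the adjusted p was 0.011 to 0.017. FOS rose by 5.38 ± 0.12 to 5.95 ± 0.13, DUSP1 by 3.90 ± 0.10 to 4.51 ± 0.11, ZFP36 by 3.60 ± 0.08 to 4.40 ± 0.09 and JUN by 3.52 ± 0.08 to 4.09 ± 0.08. For NF-kB and epithelial cytokines, 19, 19, 18 and 15 of the 23 tested members rose and 2, 2, 1 and 3 fell, or 19, 19, 19 and 15 and 3, 3, 1 and 3 adjusted over the list alone. The medians of log2 change were 1.68, 1.59, 1.32 and 1.30, with camera adjusted p = 1.2e-06 to 0.0030. An estimated correlation gave an adjusted p of 0.31 to 0.48. Within it TNFAIP3 rose by 1.30 ± 0.09 to 1.46 ± 0.09, CXCL2 by 3.89 ± 0.28 to 4.21 ± 0.28, PTGS2 by 2.55 ± 0.21 to 3.09 ± 0.21 and IL6 by 5.32 ± 0.41 to 5.84 ± 0.39, IL6 standing at 6.40 ± 3.72 CPM with the Palmetto cartridge. For EGFR ligands and ERK feedback, 11, 10, 13 and 11 of the 16 tested members rose and 3, 2, 1 and 3 fell, or 11, 11, 13 and 11 and 3, 2, 1 and 3 adjusted over the list alone. Its median log2 changes were 1.19, 1.68, 1.56 and 1.05, with camera adjusted p = 5.0e-07 to 0.00036. The adjusted p with an estimated correlation was 0.31 to 0.42. IER3, also in the list of immediate early genes, rose by 3.97 ± 0.17 to 4.57 ± 0.18. HBEGF rose by 3.21 ± 0.16 to 4.44 ± 0.17, AREG by 3.59 ± 0.20 to 4.30 ± 0.20 and DUSP5 by 4.22 ± 0.22 to 4.95 ± 0.23. Only the immediate early genes held their camera call with an estimated correlation in all 4 distillates. By fry, which asks whether a list's own genes move 1 way, their adjusted p was 1.9e-18 to 4.1e-17.

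**Figure D3:**
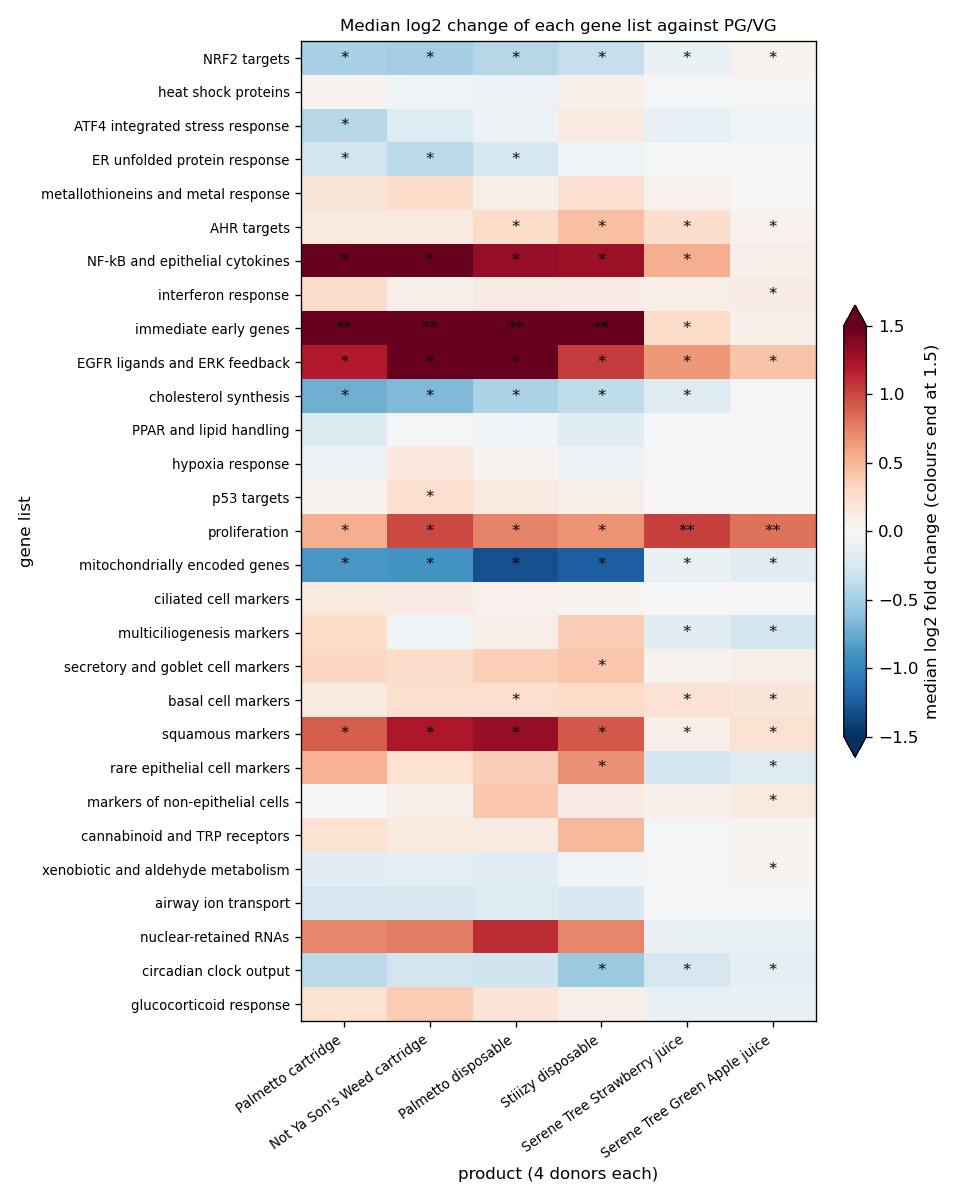
Median log2 fold change of each of the 29 gene lists (rows) in the 6 products (columns, 4 donors each) against PG/VG control, with colours ending at 1.5. One star marks a camera adjusted p under 0.05 and a pair of stars a call that held with an estimated correlation, which only immediate early genes (distillates) and proliferation (juices) did.

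Lists of lipid and stress genes moved down or in both directions with the distillates. For cholesterol synthesis, 0, 1, 1 and 0 of the 21 tested members rose and 20, 20, 19 and 14 fell, or 0, 1, 1 and 1 and 20, 20, 19 and 15 adjusted over the list alone. Medians on the log2 scale were -0.73, -0.66, -0.47 and -0.39, with camera adjusted p = 3.0e-11 to 5.8e-05. Under an estimated correlation adjusted p = 0.24 to 0.41. DHCR7 changed by -1.09 ± 0.08 to -0.74 ± 0.08. For NRF2 targets, 1, 1, 0 and 3 of the 22 tested members rose and 15, 18, 15 and 12 fell, or 1, 1, 0 and 3 and 16, 18, 16 and 12 adjusted over the list alone. In the list the median log2 changes were -0.49, -0.51, -0.42 and -0.35, with camera adjusted p = 0.00012 to 0.017. With an estimated correlation the adjusted p was 0.38 to 0.48, and GCLC changed by -0.65 ± 0.07 to -0.43 ± 0.07. For ER unfolded protein response, 0, 0, 0 and 1 of the 17 tested members rose and 14, 16, 14 and 5 fell, or 0, 0, 0 and 1 and 14, 16, 14 and 5 adjusted over the list alone. Median log2 changes were -0.28, -0.40, -0.27 and -0.07. Its camera adjusted p was 5.9e-06 to 0.00024 in the first 3 and 0.24 with the Stiiizy disposable, the 3 calls were lost with an estimated correlation (adjusted p = 0.38 to 0.43), and the Palmetto cartridge's median became 0.061 with ERCC factors. SEL1L changed by -0.62 ± 0.08 to -0.46 ± 0.08. For ATF4 integrated stress response, 4, 4, 7 and 9 of the 21 tested members rose and 13, 9, 7 and 7 fell, or 4, 4, 7 and 9 and 13, 10, 7 and 7 adjusted over the list alone. The medians of log2 change were -0.42, -0.21, -0.09 and 0.14, and camera called a fall with the Palmetto cartridge (adjusted p = 0.037, 0.51 with an estimated correlation; 0.25 to 0.60 in the others). Tested directly, the list was lower with the Palmetto cartridge than with the Palmetto disposable (adjusted p = 5.1e-17, 0.034 with an estimated correlation) and the Stiiizy disposable (1.0e-21, 0.020), and the difference from the Not Ya Son's Weed cartridge (4.2e-11, 0.16) was lost with that correlation. In it GDF15 rose by 2.89 ± 0.17 to 4.70 ± 0.18, ATF3 by 2.06 ± 0.11 to 2.69 ± 0.11 and PPP1R15A by 1.24 ± 0.07 to 1.58 ± 0.07. ATF3 is also in the list of immediate early genes and GDF15 in that of p53 targets. GDF15 (GRCh38 chromosome 19, 18374731 to 18389176) was at 1149 ± 364 CPM against 46.3 ± 21.2 CPM with the Palmetto disposable. For PPAR and lipid handling, 5, 6, 7 and 4 of the 20 tested members rose and 11, 8, 8 and 10 fell, or 5, 6, 8 and 5 and 11, 8, 8 and 10 adjusted over the list alone. Its median log2 changes were -0.22, -0.01, -0.05 and -0.18, with camera adjusted p = 0.18 to 0.62. Within it SCD changed by -1.29 ± 0.07 to -0.72 ± 0.07, TXNIP by -1.50 ± 0.08 to -0.88 ± 0.08 and ACADVL by 0.66 ± 0.07 to 0.81 ± 0.08.

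For heat shock proteins, 6, 4, 2 and 6 of the 19 tested members rose and 1, 1, 6 and 0 fell, or 6, 4, 2 and 6 and 0, 1, 6 and 0 adjusted over the list alone. Medians on the log2 scale were 0.06, -0.06, -0.09 and 0.10, with camera adjusted p = 0.16 to 0.97. CHORDC1 rose by 0.74 ± 0.09 to 1.13 ± 0.09. For metallothioneins and metal response, 4, 4, 3 and 4 of the 8 tested members rose and 1, 1, 0 and 1 fell, or 4, 4, 3 and 4 and 1, 2, 0 and 1 adjusted over the list alone. In the list the median log2 changes were 0.18, 0.28, 0.09 and 0.24, with camera adjusted p = 0.23 to 0.60. MT2A rose by 0.64 ± 0.09 to 1.05 ± 0.09. For AHR targets, 3, 5, 4 and 5 of the 9 tested members rose and 1, 0, 0 and 1 fell, or 3, 5, 4 and 5 and 1, 0, 0 and 1 adjusted over the list alone. Median log2 changes were 0.15, 0.14, 0.28 and 0.46. Camera called both disposables (adjusted p = 0.041 and 0.035, but 0.39 with an estimated correlation) and gave 0.071 to 0.18 for the cartridges, but no difference passed in the list between any pair of distillates (0.060 to 0.69). CYP1A1 rose by 2.77 ± 0.29 to 3.84 ± 0.28, to 8.65 ± 2.34 CPM against 0.678 ± 0.513 CPM with the Stiiizy disposable, TIPARP by 1.42 ± 0.11 to 1.64 ± 0.11 and CYP1B1 by 0.68 ± 0.15 to 1.54 ± 0.15. For interferon response, 9, 4, 5 and 2 of the 18 tested members rose and 1, 3, 2 and 3 fell, or 9, 4, 4 and 1 and 1, 3, 2 and 3 adjusted over the list alone. The medians of log2 change were 0.27, 0.08, 0.12 and 0.12, with camera adjusted p = 0.15 to 0.97. For hypoxia response, 4, 8, 5 and 4 of the 16 tested members rose and 5, 3, 7 and 4 fell, or 4, 8, 5 and 4 and 5, 3, 7 and 4 adjusted over the list alone. Its median log2 changes were -0.08, 0.16, 0.04 and -0.08, with camera adjusted p = 0.19 to 0.98, and VEGFA rose by 1.88 ± 0.11 to 3.21 ± 0.12. For p53 targets, 7, 9, 8 and 7 of the 16 tested members rose and 1, 2, 4 and 4 fell, or 7, 9, 8 and 7 and 1, 2, 4 and 4 adjusted over the list alone. Medians on the log2 scale were 0.06, 0.25, 0.14 and 0.09. The Not Ya Son's Weed cartridge had a camera adjusted p = 0.038 (0.20 with an estimated correlation) and the others 0.061 to 0.23, but no difference passed in the list between it and the disposables (0.11 to 0.88). The list was lower with the Palmetto cartridge than with the Not Ya Son's Weed cartridge (adjusted p = 0.00069, 0.024 with an estimated correlation). PLK3 rose by 1.27 ± 0.10 to 1.73 ± 0.10.

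Of the 13 protein genes encoded in mitochondria, 13 fell with every distillate (also 13 adjusted over the list alone), with median log2 changes of -0.87, -0.90, -1.32 and -1.24 for the list of mitochondrially encoded genes and camera adjusted p = 4.6e-15 to 1.2e-10. An estimated correlation gave an adjusted p of 0.20 to 0.26. MT-ND2 changed by -1.40 ± 0.07 to -0.98 ± 0.07 and MT-ND3 by -1.46 ± 0.08 to -1.07 ± 0.08, and MT-ND2 stood at 1765 ± 234 CPM against 4657 ± 708 CPM with the Palmetto disposable. For proliferation, 13, 13, 13 and 15 of the 16 tested members rose and 0 fell, or 14, 13, 13 and 15 and 0 adjusted over the list alone. In the list the median log2 changes were 0.54, 0.99, 0.74 and 0.67, with camera adjusted p = 4.5e-06 to 0.0021. The adjusted p with an estimated correlation was 0.32 to 0.47. TYMS rose by 0.89 ± 0.11 to 1.15 ± 0.11 and RRM2 by 1.11 ± 0.17 to 1.57 ± 0.16. For nuclear-retained RNAs, 4, 4, 5 and 4 of the 8 tested members rose and 2 fell, or 4, 4, 5 and 4 and 2 adjusted over the list alone. Median log2 changes were 0.73, 0.77, 1.11 and 0.73, with camera adjusted p = 0.22 to 0.37. MALAT1 (GRCh38 chromosome 11, 65497640 to 65508073) rose by 2.79 ± 0.19 to 3.13 ± 0.19, NEAT1 (GRCh38 chromosome 11, 65422774 to 65445540) by 1.87 ± 0.16 to 2.10 ± 0.16 and KCNQ1OT1 by 1.96 ± 0.18 to 2.10 ± 0.18, while NORAD changed by -0.64 ± 0.07 to -0.48 ± 0.07. MALAT1 stood at 2318 ± 1346 CPM against 311 ± 129.6 CPM with the Palmetto cartridge (adjusted p = 1.3e-12). Where the list's members lie in these cells was not measured, so the fall of NORAD need not be that of a nuclear RNA.

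Marker lists of airway cell types were tested in the same way. For ciliated cell markers, 6, 6, 3 and 4 of the 17 tested members rose and 3, 0, 2 and 2 fell, or 8, 6, 3 and 1 and 3, 0, 2 and 2 adjusted over the list alone. The medians of log2 change were 0.14, 0.13, 0.07 and 0.04, with camera adjusted p = 0.36 to 0.77. DNAI1 rose by 0.41 ± 0.07 to 0.58 ± 0.07, but with ERCC factors its change with the Stiiizy disposable was -0.011. For multiciliogenesis markers, 6, 1, 2 and 8 of the 10 tested members rose and 2, 2, 0 and 1 fell, or 7, 1, 1 and 8 and 2, 2, 0 and 1 adjusted over the list alone. Its median log2 changes were 0.28, -0.07, 0.10 and 0.37, with camera adjusted p = 0.053 to 0.76. FOXN4 rose by 0.64 ± 0.13 to 1.02 ± 0.13. For secretory and goblet cell markers, 10, 10, 12 and 11 of the 19 tested members rose and 0, 1, 2 and 0 fell, or 10, 10, 12 and 12 and 0, 1, 2 and 0 adjusted over the list alone. Medians on the log2 scale were 0.31, 0.27, 0.35 and 0.42. Camera called the Stiiizy disposable (adjusted p = 0.0060, 0.31 with an estimated correlation), whose median was -0.007 with ERCC factors, with adjusted p = 0.085 to 0.17 in the others. The differences from these had adjusted p = 0.012 to 0.043 (0.36 to 0.44 with an estimated correlation). MUC16 rose by 0.81 ± 0.15 to 0.85 ± 0.15. For basal cell markers, 7, 8, 8 and 8 of the 15 tested members rose and 3, 3, 1 and 3 fell, or 7, 8, 8 and 8 and 3, 3, 1 and 3 adjusted over the list alone. In the list the median log2 changes were 0.13, 0.24, 0.26 and 0.29. The Palmetto disposable was called (adjusted p = 0.018, 0.45 with an estimated correlation, and a median of -0.003 with ERCC factors), against 0.081 to 0.26 in the others, but no difference passed in the list between it and the Not Ya Son's Weed cartridge (0.12) or the Stiiizy disposable (0.12). The difference from the Palmetto cartridge passed (adjusted p = 0.0065, 0.43 with an estimated correlation). KRT17 rose by 1.14 ± 0.10 to 1.73 ± 0.10 and KRT14 by 1.16 ± 0.18 to 1.69 ± 0.18. For squamous markers, 11, 13, 13 and 11 of the 15 tested members rose and 0, 1, 0 and 0 fell, or 11, 13, 13 and 11 and 0, 1, 1 and 0 adjusted over the list alone. Median log2 changes were 0.90, 1.21, 1.31 and 0.92, with camera adjusted p = 5.5e-06 to 0.0019. Under an estimated correlation adjusted p = 0.099 to 0.26. KRT16 rose by 2.07 ± 0.18 to 2.85 ± 0.18. For markers of non-epithelial cells, 2, 3, 3 and 2 of the 9 tested members rose and 1 fell, or 2, 3, 3 and 2 and 1 adjusted over the list alone. The medians of log2 change were -0.01, 0.08, 0.40 and 0.12, with camera adjusted p = 0.19 to 0.53. COL1A1 rose by 1.35 ± 0.16 to 1.64 ± 0.16.

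Serene Tree Strawberry juice called 1370 genes against PG/VG control, and 771, 707 and 571 without replicate 1, 2 and 3, a replicate being a donor. The 10 largest rises were 3.33 ± 0.49 for ANXA10, 2.42 ± 0.23 for MKI67, 2.37 ± 0.21 for PIMREG, 2.34 ± 0.25 for SPC25 and 2.25 ± 0.21 for CEP55. After them came 2.09 ± 0.22 for DEPDC1B, 2.08 ± 0.24 for IQGAP3, 2.07 ± 0.27 for AURKB, 2.05 ± 0.24 for ASPM and 2.02 ± 0.17 for CCNA2. MKI67 (GRCh38 chromosome 10, 128096659 to 128126423), a gene of dividing cells, was at 22.7 ± 8.27 CPM against 4.26 ± 1.42 CPM (adjusted p = 3.1e-08). The level of ANXA10, 1.70 ± 3.22 CPM against 0.158 ± 0.298 CPM, rested largely on 1 of 4 donors. That donor had a log2 ratio of 2.668 and the others 0.107 to 0.389. These ratios carry a pseudocount of 0.5 CPM, which holds down ratios at levels under it. The largest falls were -2.01 ± 0.17 for BACH2, -1.46 ± 0.16 for CDH6, -1.15 ± 0.16 for SLC2A4, -1.10 ± 0.15 for MYL9 and -1.03 ± 0.28 for OLFML2B. Next in size were -1.02 ± 0.18 for SPNS2, -0.99 ± 0.23 for CHRM4, -0.97 ± 0.26 for PHACTR1, -0.97 ± 0.22 for OR51E1 and -0.92 ± 0.12 for MSRB3. BACH2 stood at 1.67 ± 0.246 CPM against 6.79 ± 0.993 CPM (adjusted p = 6.4e-09).

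By camera, 12 lists passed with Strawberry juice. All 16 genes of the proliferation list rose (16 adjusted over the list alone). For its members the median was 1.03, with camera adjusted p = 4.7e-37 (0.0062 with an estimated correlation), and fry gave them an adjusted p = 1.3e-08. In the list immediate early genes, 7 of 24 rose and 0 fell, or 10 and 0 adjusted over the list alone. Median log2 change there was 0.27, with camera adjusted p = 7.9e-08 (0.26 with an estimated correlation), and EGR1 rose by 0.88 ± 0.15. In EGFR ligands and ERK feedback, 8 of 16 rose and 0 fell, or 11 and 1 adjusted over the list alone. Members had a median of 0.65, with camera adjusted p = 1.7e-07 (0.30 with an estimated correlation), and ETV4 rose by 1.58 ± 0.21. In NF-kB and epithelial cytokines, 0 of 23 rose and 1 fell, or 8 and 1 adjusted over the list alone. The median log2 change was 0.55, with camera adjusted p = 0.00064 (0.43 with an estimated correlation). In AHR targets, 3 of 9 rose and 0 fell, or 5 and 0 adjusted over the list alone. Its median log2 change was 0.26, with camera adjusted p = 0.00061 (0.23 with an estimated correlation), and CYP1B1 rose by 0.66 ± 0.15. In basal cell markers, 4 of 15 rose and 0 fell, or 8 and 0 adjusted over the list alone. The list had a median log2 change of 0.22, with camera adjusted p = 5.1e-05 (0.26 with an estimated correlation), and COL17A1 rose by 0.93 ± 0.12. In squamous markers, 3 of 15 rose and 0 fell, or 4 and 0 adjusted over the list alone. Here the median log2 change was 0.09, with camera adjusted p = 0.045 (0.41 with an estimated correlation).

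Medians of the lists that were lower in Strawberry juice turned positive with ERCC factors, which moved the median of all genes to 0.33. The list medians given here all stayed below that value. In cholesterol synthesis, 0 of 21 rose and 8 fell, or 1 and 11 adjusted over the list alone. On the log2 scale the median was -0.20, with camera adjusted p = 7.9e-08 (0.31 with an estimated correlation), and a median of 0.17 with ERCC factors. HMGCS1 changed by -0.78 ± 0.09. In NRF2 targets, 0 of 22 rose and 3 fell, or 1 and 6 adjusted over the list alone. For its members the median was -0.10, with camera adjusted p = 0.043 (0.53 with an estimated correlation), and a median of 0.25 with ERCC factors. In mitochondrially encoded genes, 0 of 13 rose and 0 fell, or 0 and 0 adjusted over the list alone. Median log2 change there was -0.10, with camera adjusted p = 0.033 (0.61 with an estimated correlation), and a median of 0.24 with ERCC factors. In multiciliogenesis markers, 0 of 10 rose and 2 fell, or 0 and 3 adjusted over the list alone. Members had a median of -0.17, with camera adjusted p = 0.043 (0.48 with an estimated correlation), and a median of 0.20 with ERCC factors. In circadian clock output, 0 of 15 rose and 7 fell, or 0 and 8 adjusted over the list alone. The median log2 change was -0.25, with camera adjusted p = 0.00015 (0.11 with an estimated correlation), and a median of 0.10 with ERCC factors. CIART changed by -0.70 ± 0.10. For lists without a call with Strawberry juice the camera adjusted p was, for heat shock proteins 0.68, ATF4 integrated stress response 0.078, ER unfolded protein response 0.36, metallothioneins and metal response 0.29 and interferon response 0.12. For others it was, for PPAR and lipid handling 0.97, hypoxia response 0.81, p53 targets 0.81, ciliated cell markers 0.83 and secretory and goblet cell markers 0.44. It was also, for rare epithelial cell markers 0.066, markers of non-epithelial cells 0.22, cannabinoid and TRP receptors 0.98, xenobiotic and aldehyde metabolism 0.95 and airway ion transport 0.92. It further was, for nuclear-retained RNAs 0.56 and glucocorticoid response 0.18.

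Serene Tree Green Apple juice called 477 genes against PG/VG control, and 253 and 266 without replicate 1 and 3. The 10 largest rises were 3.20 ± 0.50 for ANXA10, 2.56 ± 0.25 for SPC25, 2.35 ± 0.21 for CEP55, 2.19 ± 0.21 for PIMREG and 2.06 ± 0.27 for AURKB. Then came 2.02 ± 0.23 for ESCO2, 2.01 ± 0.20 for HJURP, 2.00 ± 0.16 for PBK, 2.00 ± 0.18 for MYBL2 and 1.99 ± 0.16 for BIRC5. BIRC5 was at 11.3 ± 1.81 CPM against 2.85 ± 0.394 CPM (adjusted p = 4.2e-09). ANXA10 stood at 1.45 ± 2.68 CPM against 0.158 ± 0.298 CPM, with an SD larger than its mean, as with Strawberry juice. The largest falls were -1.52 ± 0.35 for ATF7-NPFF, -0.99 ± 0.24 for MASP2, -0.99 ± 0.21 for COL14A1, -0.94 ± 0.23 for RBFOX1 and -0.92 ± 0.21 for HIF3A. These were followed by -0.91 ± 0.22 for SLC34A3, -0.88 ± 0.16 for BACH2, -0.84 ± 0.19 for FBN1 and -0.84 ± 0.22 for OR51E1.

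All 16 genes of the proliferation list rose with Green Apple juice too (16 adjusted over the list alone). Its median log2 change was 0.81, with camera adjusted p = 9.8e-41 (0.0062 with an estimated correlation) and a fry adjusted p = 4.0e-08. In EGFR ligands and ERK feedback, 3 of 16 rose and 0 fell, or 8 and 0 adjusted over the list alone. The list had a median log2 change of 0.43, with camera adjusted p = 0.00010 (0.39 with an estimated correlation), and ETV4 rose by 1.43 ± 0.21. In basal cell markers, 4 of 15 rose and 0 fell, or 6 and 0 adjusted over the list alone. Here the median log2 change was 0.18, with camera adjusted p = 8.5e-05 (0.27 with an estimated correlation). In squamous markers, 4 of 15 rose and 0 fell, or 4 and 0 adjusted over the list alone. On the log2 scale the median was 0.23, with camera adjusted p = 0.0019 (0.26 with an estimated correlation), and KRT13 rose by 1.23 ± 0.20. In AHR targets, 1 of 9 rose and 0 fell, or 2 and 0 adjusted over the list alone. For its members the median was 0.07, with camera adjusted p = 0.041 (0.39 with an estimated correlation), and ALDH3A1 rose by 0.60 ± 0.09. In NRF2 targets, 1 of 22 rose and 0 fell, or 3 and 0 adjusted over the list alone. Median log2 change there was 0.06, with camera adjusted p = 0.045 (0.54 with an estimated correlation). In xenobiotic and aldehyde metabolism, 1 of 22 rose and 0 fell, or 4 and 0 adjusted over the list alone. Members had a median of 0.05, with camera adjusted p = 0.044 (0.48 with an estimated correlation).

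Other lists passed camera for Green Apple juice with few or no called members. In mitochondrially encoded genes, 0 of 13 rose and 0 fell, or 0 and 1 adjusted over the list alone. The median log2 change was -0.17, with camera adjusted p = 0.00039 (0.48 with an estimated correlation). In multiciliogenesis markers, 0 of 10 rose and 2 fell, or 0 and 7 adjusted over the list alone. Its median log2 change was -0.27, with camera adjusted p = 5.5e-05 (0.26 with an estimated correlation), and MCIDAS changed by -0.53 ± 0.11. In rare epithelial cell markers, 0 of 14 rose and 3 fell, or 0 and 3 adjusted over the list alone. The list had a median log2 change of -0.20, with camera adjusted p = 0.031 (0.38 with an estimated correlation). In circadian clock output, 0 of 15 rose and 0 fell, or 0 and 0 adjusted over the list alone. Here the median log2 change was -0.15, with camera adjusted p = 0.0021 (0.20 with an estimated correlation). In interferon response, 0 of 18 rose and 0 fell, or 1 and 0 adjusted over the list alone. On the log2 scale the median was 0.11, with camera adjusted p = 0.042 (0.61 with an estimated correlation). In markers of non-epithelial cells, 1 of 9 rose and 0 fell, or 1 and 0 adjusted over the list alone. For its members the median was 0.15, with camera adjusted p = 0.045 (0.32 with an estimated correlation). For lists without a call the camera adjusted p was, for heat shock proteins 0.59, ATF4 integrated stress response 0.31, ER unfolded protein response 0.34, metallothioneins and metal response 0.86 and NF-kB and epithelial cytokines 0.58. For others it was, for immediate early genes 0.12, cholesterol synthesis 0.20, PPAR and lipid handling 0.99, hypoxia response 0.76 and p53 targets 0.68. It was also, for ciliated cell markers 0.92, secretory and goblet cell markers 0.22, cannabinoid and TRP receptors 0.55, airway ion transport 0.86 and nuclear-retained RNAs 0.072. It further was, for glucocorticoid response 0.054.

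**Figure D4:**
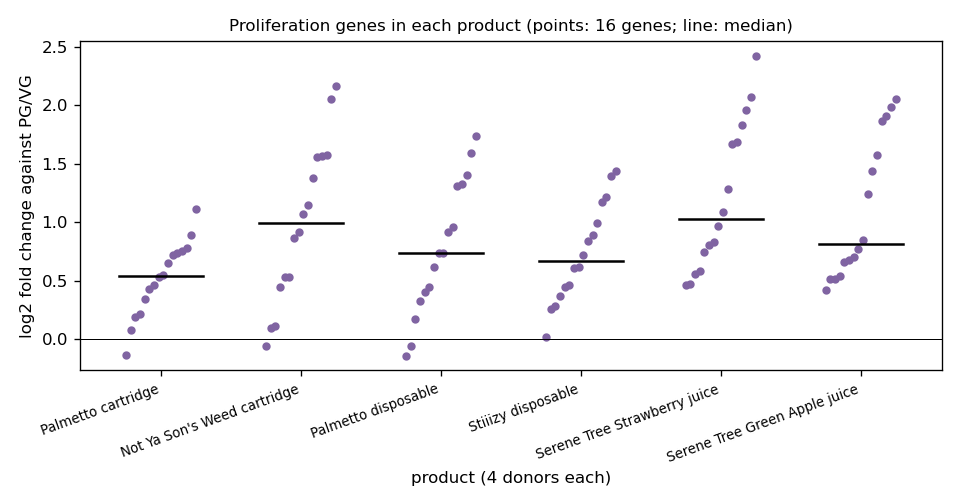
Log2 fold change against PG/VG control (vertical axis) of the 16 proliferation genes in each of the 6 products (4 donors each); points are genes and lines their median. The medians are 1.03 for Strawberry and 0.81 for Green Apple juice and 0.54, 0.99, 0.74 and 0.67 for the distillates from left to right.

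The mean of the 4 distillates was compared with the mean of both juices to set these products apart, although the devices differed too. P-values of this comparison and its list tests rest on the spread left after the group and donor terms. They do not measure the spread between products of a kind, and both juices are from Serene Tree. EdgeR called 14802 genes, 7489 higher and 7313 lower with distillates, and 2730 rose and 64 fell at least 2-fold. The share of higher genes was 50.6% with TMM and 24.3% with ERCC factors, which moved the median of all genes to -0.33. Largest rises were 7.14 ± 0.19 for NR4A1AS, 6.47 ± 0.32 for MIR616, 6.00 ± 0.23 for C11orf96, 5.74 ± 0.15 for FOSB and 5.71 ± 0.18 for MIR3189. The next were 5.57 ± 0.11 for RASD1, 5.43 ± 0.12 for NR4A1, 5.32 ± 0.18 for ARC, 5.30 ± 0.08 for FOS and 4.77 ± 0.24 for IL20. Largest falls were -2.30 ± 0.11 for MT-TW, -2.26 ± 0.10 for MT-TS2, -2.23 ± 0.07 for MT-TL2, -2.16 ± 0.12 for MT-TH and -2.07 ± 0.13 for MT-TG. After them came -1.64 ± 0.05 for MT-TN, -1.62 ± 0.05 for MT-TC, -1.48 ± 0.10 for FAM131B, -1.47 ± 0.08 for S1PR5 and -1.35 ± 0.12 for MT-TF. FOS was at 1743 ± 124 CPM against 44.04 ± 4.57 CPM with juices (adjusted p = 9.5e-29), and MALAT1 at 2472 ± 1349 CPM against 232 ± 69.95 CPM.

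Of the lists compared between distillates and juices, only 1 call held with an estimated correlation. Among immediate early genes, 24 of 24 rose and 0 fell, or 24 and 0 adjusted over the list alone. Median log2 change there was 2.98, with camera adjusted p = 2.2e-20 (0.033 with an estimated correlation). Of mitochondrially encoded genes, 0 of 13 rose and 13 fell, or 0 and 13 adjusted over the list alone. Members had a median of -0.94, with camera adjusted p = 3.8e-10 (0.27 with an estimated correlation). For cholesterol synthesis, 1 of 21 rose and 20 fell, or 1 and 20 adjusted over the list alone. The median log2 change was -0.43, with camera adjusted p = 1.9e-06 (0.38 with an estimated correlation). Among NRF2 targets, 0 of 22 rose and 19 fell, or 0 and 19 adjusted over the list alone. Its median log2 change was -0.34, with camera adjusted p = 0.00012 (0.38 with an estimated correlation). For ER unfolded protein response, 0 of 17 rose and 15 fell, or 0 and 16 adjusted over the list alone. The list had a median log2 change of -0.22, with camera adjusted p = 0.0012 (0.48 with an estimated correlation). Within xenobiotic and aldehyde metabolism, 2 of 22 rose and 15 fell, or 2 and 15 adjusted over the list alone. Here the median log2 change was -0.25, with camera adjusted p = 0.041 (0.48 with an estimated correlation).

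In NF-kB and epithelial cytokines, 18 of 23 rose and 3 fell, or 18 and 3 adjusted over the list alone. On the log2 scale the median was 1.06, with camera adjusted p = 0.00024 (0.41 with an estimated correlation). In EGFR ligands and ERK feedback, 10 of 16 rose and 5 fell, or 10 and 5 adjusted over the list alone. For its members the median was 1.01, with camera adjusted p = 0.015 (0.51 with an estimated correlation). By contrast, in proliferation, 0 of 16 rose and 14 fell, or 0 and 15 adjusted over the list alone. Median log2 change there was -0.37, with camera adjusted p = 0.0010 (0.43 with an estimated correlation). Of the squamous markers, 11 of 15 rose and 2 fell, or 11 and 2 adjusted over the list alone. Members had a median of 0.91, with camera adjusted p = 0.0030 (0.27 with an estimated correlation). For rare epithelial cell markers, 11 of 14 rose and 0 fell, or 12 and 0 adjusted over the list alone. The median log2 change was 0.50, with camera adjusted p = 0.0061 (0.30 with an estimated correlation). Among multiciliogenesis markers, 7 of 10 rose and 1 fell, or 7 and 1 adjusted over the list alone. Its median log2 change was 0.46, with camera adjusted p = 0.026 (0.47 with an estimated correlation). In the glucocorticoid response, 7 of 11 rose and 1 fell, or 7 and 1 adjusted over the list alone. The list had a median log2 change of 0.32, with camera adjusted p = 0.034 (0.39 with an estimated correlation), and -0.015 with ERCC factors. PCNA changed by -0.51 ± 0.04 and BIRC5 by -1.08 ± 0.09. For lists without a call between distillates and juices the camera adjusted p was, for heat shock proteins 0.47, ATF4 integrated stress response 0.86, metallothioneins and metal response 0.48, AHR targets 0.63 and interferon response 0.87. For others it was, for PPAR and lipid handling 0.40, hypoxia response 0.58, p53 targets 0.16, ciliated cell markers 0.53 and secretory and goblet cell markers 0.15. It was also, for basal cell markers 0.91, markers of non-epithelial cells 0.76, cannabinoid and TRP receptors 0.31, airway ion transport 0.10 and nuclear-retained RNAs 0.24. It further was, for circadian clock output 0.31.

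Both juices used 1 device, and their direct comparison called 490 genes, 301 higher and 189 lower with Strawberry, of which 16 and 2 changed at least 2-fold. The share of higher genes went from 61.4% with TMM to 77.1% with total counts and 99.2% with ERCC factors, and ERCC moved the median of all genes to 0.24. The count depended on the donors and the fit, with 267, 156, 83 and 276 called genes without replicate 1, 2, 3 and 4, and 5 when only the juice libraries were fitted. Larger with Strawberry were 1.84 ± 0.44 for STC1, 1.25 ± 0.18 for SOCS3, 1.10 ± 0.17 for KCNQ5, 1.05 ± 0.19 for CHAC1 and 1.02 ± 0.22 for DEPP1. STC1 (GRCh38 chromosome 8, 23841929 to 23854806) stood at 1.65 ± 1.51 CPM against 0.416 ± 0.238 CPM (adjusted p = 0.021). Smaller were -1.13 ± 0.18 for BACH2, -0.98 ± 0.12 for MSRB3, -0.76 ± 0.18 for GLIPR1, -0.73 ± 0.16 for CDH6 and -0.72 ± 0.18 for SLCO2A1. BACH2 was at 1.67 ± 0.246 CPM against 3.70 ± 0.807 CPM. By camera on the difference itself, cholesterol synthesis (3.0e-06, 0.38 with an estimated correlation) and NRF2 targets (7.3e-06, 0.35) were lower with Strawberry (adjusted p over all list differences tested). Direction was up for immediate early genes (2.1e-05, 0.37) and up for NF-kB and epithelial cytokines (0.0034, 0.50).

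Any difference among the 4 distillates was tested over the 3 contrasts between them, and 3930 genes were called, with 1962, 2144 and 1886 without replicate 1, 2 and 3. With ERCC factors the count was 17991, and 6859 when only the distillates were fitted. The smallest p belonged to TUFT1 (GRCh38 chromosome 1, 151540305 to 151583583). In the order above, TUFT1 levels were 84.4 ± 15.5, 121 ± 16.4, 37.5 ± 5.90 and 49.1 ± 9.21 CPM, against 23.6 ± 1.29 CPM in the control (adjusted p = 2.0e-12). STX1A stood at 10.2 ± 2.66, 15.8 ± 3.43, 25.5 ± 5.96 and 13.01 ± 4.08 CPM (control 9.58 ± 2.26, adjusted p = 1.5e-10). FN1 was at 61.7 ± 47.2, 23.2 ± 15.8, 28.1 ± 22.3 and 74.4 ± 55.8 CPM (control 16.5 ± 11.4, adjusted p = 1.5e-10). HES1 levels were 202 ± 39.8, 233 ± 17.6, 375 ± 50.3 and 386 ± 40.3 CPM (control 48.9 ± 4.83, adjusted p = 3.0e-10) and those of VEGFA 198 ± 53.03, 242 ± 62.9, 498 ± 113 and 389 ± 94.6 CPM (control 53.2 ± 12.2, adjusted p = 1.0e-09). KRT16P2, IFFO2, EMP1, IER5L and CLCF1 completed the 10 smallest p, with adjusted p = 5.1e-10, 5.1e-10, 6.3e-10, 7.4e-10 and 1.0e-09.

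Products shared the control libraries, which by itself makes their changes alike. In all 4 distillates 3879 genes were called higher and 3619 lower, and 12 were called in all 4 but not 1 way. Across genes, which are not independent replicates, log2 changes of distillate pairs correlated with Pearson r = 0.893 to 0.932. In 100 simulations of unchanged groups against the same controls, r was 0.501, a value that sharing 1 control fixes under independent noise of equal spread. The covariance was 0.349 to 0.388, against 0.0188 simulated. When control well 1 served 1 product and control well 2 the other, r was 0.804 to 0.850. For the Palmetto and Not Ya Son's Weed cartridges, 5158 genes rose and 4831 fell in both, where independent lists would share 1747.2 and 1460.4. Both juices shared 259 higher and 39 lower genes, or 216 and 15 with split controls, where independent lists would share 13.9 and 3. The simulated groups shared 0, but they were unchanged, so few calls could arise in them to be shared. Across genes the juices had r = 0.615, or 0.324 and 0.23 with split controls. Their covariance was 0.0475, or 0.0294 with split controls. Distillates and Strawberry juice had r = 0.216 to 0.269, or 0.119 to 0.198 with split controls. Their covariance was 0.0386 to 0.0478, above the simulated 0.0188 although r was below the simulated one. Distillates and Green Apple juice had r = -0.041 to -0.016, or -0.124 to -0.031 with split controls, and a covariance of -0.0071 to -0.003. In all 6 products 138 genes were called higher and 19 lower.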

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

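The test of genomic DNA was run more than once, and its second and per-kilobase versions, the test of abundant transcripts and the test of basal cells were chosen only after the result was seen. For 2 tests the verdict bound was also changed after the value was known, and for nuclear dilution an argument was added then, as stated with each. A donor stood far from the other 3 (Dixon's ratio of gap to range past its 5% critical value) in 16 of 359 sets of gene log2 ratios, and in 7 of 63 sets of library measures, where chance gives about 1 in 20. The ratios for genes were TMEM97 with the Not Ya Son's Weed cartridge 0.8634, FOSB with the Palmetto disposable 0.8473, ZFP36 with the Stiiizy disposable 0.8966, DHCR7 with the Stiiizy disposable 0.9689, GDF15 with the Stiiizy disposable 0.9488, PPP1R15A with the Palmetto cartridge 0.9326, TXNIP with the Stiiizy disposable 0.8465, DNAI1 with the Palmetto cartridge 0.9139, COL1A1 with the Not Ya Son's Weed cartridge 0.8365, COL1A1 with the Palmetto disposable 0.959, ANXA10 with the Strawberry juice 0.8898, CHRM4 with the Strawberry juice 0.8323, EGR1 with the Strawberry juice 0.8657, CYP1B1 with the Strawberry juice 0.9504, AURKB with the Green Apple juice 0.8577, PER1 with the Palmetto cartridge 0.8642. The ratios for library measures were total counts for Palmetto disposable 0.8792, counts in the genes used for Palmetto disposable 0.9583, ERCC share for PG/VG control 0.8814, mitochondrial share for Strawberry juice 0.9033, genes detected for Stiiizy disposable 0.8868, share of the 10 highest genes for Palmetto disposable 0.9392, share of the 100 highest genes for Palmetto disposable 0.8806. ANXA10 with Strawberry juice showed 1 donor at 2.668 and the others at 0.107 to 0.389, with a pseudocount of 0.5 CPM that holds down ratios at low levels.

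Gene lists moved in opposite directions in 6 pairs of products, and the difference itself was tested by camera. NRF2 targets were lower with each distillate and with Strawberry juice than with Green Apple juice (adjusted p = 8.8e-06, 8.9e-06, 1.5e-05, 0.0014 and 7.3e-06), but with an estimated correlation the differences did not pass, at adjusted p = 0.35 for Strawberry, both cartridges and the Palmetto disposable and 0.45 for the Stiiizy disposable. With ERCC factors the list medians of Strawberry and Green Apple juice were 0.25 and 0.17, both positive. The medians of all genes were then 0.33 and 0.095. Relative to these the list still lay lower with Strawberry and higher with Green Apple juice. Rare epithelial cell markers were higher with the Stiiizy disposable than with Green Apple juice (adjusted p = 0.0028, 0.30 with an estimated correlation).

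MALAT1 and NEAT1 rose with all 4 distillates. Genomic DNA in the libraries was tested 3 times. All 842 olfactory receptor genes gave a distillate to juice ratio of 0.952 to 1.121 over donors, under the bound set in advance. That bound was written for genes silent in this tissue, but the sum includes genes at 1 CPM or more. The ratio of all 842 therefore cannot exclude genomic DNA. The 833 genes left by a 1 CPM limit chosen after that gave 1.351 to 1.867, which leaves it open. The gain per kilobase, also chosen after, accounted for at most 0.00245% of the MALAT1 and NEAT1 gain. A loss of abundant transcripts could lift other genes by at most 0.0338 on the log2 scale. RNA of dying or leaky cells that keep nuclei cannot be told apart from a response, because the 83 ribosomal protein genes had medians of -0.21 to -0.129, between the bounds set in advance. The products and the device stay open as untested causes.

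Proliferation genes rose with both juices. Without each donor in turn the lowest median was 0.783, so 1 donor's control wells do not account for it; the bound of 1 written in advance lay above the Green Apple median of 0.81 itself, and a bound of 0.5 was used after the value was known. More basal cells cannot be told apart. The basal markers' median was 0.222 of the proliferation median at most, under the written bound of 0.25, but their upper quartile was 0.585 of it, and a condition on this quartile was added to the bound after the value was known. A low control cannot be told apart either, because the lowest median of the 6 products was 0.54 and the series holds no culture without aerosol.

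Mitochondrially encoded RNA fell with all 4 distillates. Fewer ciliated cells would lower ciliated markers, but their lowest median was 0.041, so this does not account for the fall. A rise of nuclear RNA that dilutes it cannot be told apart, since 79 nuclear oxidative phosphorylation genes had medians of -0.138 to -0.047; the bound written in advance to exclude it was 0.1 and was not met. An argument added after the value was known is that a rise shared by all nuclear RNA would leave these genes near 0. With ERCC factors, looked at after the result was seen, the median of all genes was 0.39 with the Palmetto cartridge and -0.069, -0.24 and -0.40 with the others, and that of mitochondrially encoded genes -0.52, -0.99, -1.58 and -1.67. A rise of nuclear RNA measured against the spike-ins is thus absent in 3 of the 4, but how the spike-ins were added is not stated, so dilution stays open. A response to the distillates or their device stays open.

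Other splits of the same sums were counted, each fitted on the groups compared alone. For each product against the control, 1 of 32 splits, the real one, gave as many called genes and no other split reached it. The real counts were 9018, 9451, 8810, 9531, 1240 and 684 in the order of the distillates, Strawberry and Green Apple, and the highest other split gave 0 for each but Green Apple, with 2. The same holds between the juices, where the real split gave 5 and the highest other 1, also 1 of 32. In each of these comparisons only 7 other splits keep every donor in both groups as the real one does. The highest count among these 7 was 0. With so few such splits, 1 of 32 cannot be read as a p-value for the paired design. Every other split also mixes the groups compared, so a real difference enters its spread and can lower its count. For distillates against juices 1 of 100 splits gave as many, the real one at 14883 and the highest other at 8088, and among distillates 1 of 99, at 6859 against 730. In the last 2 comparisons the highest other value came from a split that keeps every donor in all groups as the real one does, 49 such splits being drawn for each. Also the median of the other splits was 0.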

How the results depend on the processing

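Size factors from the ERCC spike-ins and a test of protein-coding genes only were chosen after seeing the data, and the other alternatives before the data were examined. Of the counts of called genes under all alternatives, 104 lay within 1.5 times the main count and 40 did not. For named genes, 11857 values kept direction and threshold, and 587 kept the direction but lost the threshold. Another 24 reversed in sign, all with ERCC factors, and none of these passed the threshold in the new direction. Of the list results 2924 kept their camera call or stayed without one, 211 lost the threshold and 106 gained it. Lists called in both fits kept camera's direction, which is relative to other genes, while the direction of other lists was not compared. Medians of some lists changed sign with ERCC factors, as given above. These factors also moved the median of all genes, so a change of sign alone does not place a list on the other side of the bulk of genes.

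Against a main count of 477 for Green Apple juice and 490 for Strawberry against Green Apple, DESeq2 called 722 and 1038, and no filter on low counts gave 919 and 971, where more genes were tested. Wells as separate libraries, which treat wells of a donor as independent, gave 2649 for Strawberry, 1209 for Green Apple, 1927 between them and 6441 among distillates. With 1 well per donor fewer counts enter. Well 1 alone gave 7791 for the Palmetto cartridge, 553 for Strawberry, 300 for Green Apple, 156 between the juices and 1763 among distillates, and well 2 alone 297 for Green Apple and 143 between the juices. Fitting only the groups compared gave 5 between the juices and 6859 among distillates, and the cause was not tested.

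The donor term is part of the main design. Without this block the counts were 7407 for the Palmetto disposable, 7307 for the Stiiizy disposable, 272 for Strawberry, 134 for Green Apple, 23 between the juices and 676 among distillates, since differences between donors then enter the spread. Counts of the other comparisons without the block stayed within 1.5 times.

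Leaving out each replicate in turn gave 10240 to 10585 called genes for the Palmetto cartridge, 10053 to 10947 for the Not Ya Son's Weed cartridge, 9196 to 10066 for the Palmetto disposable, 9249 to 10181 for the Stiiizy disposable, 571 to 1511 for Strawberry, 253 to 436 for Green Apple, 13694 to 14041 for distillates against juices, 83 to 276 between the juices and 1886 to 4747 among distillates. Fewer donors enter these fits.

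With ERCC factors the counts were 7551 for the Not Ya Son's Weed cartridge, 4474 for Strawberry, 303 for Green Apple, 746 between the juices and 17991 among distillates. The log2 changes that reversed with them were, for the Palmetto cartridge, RRM2B 0.08; for the Palmetto disposable, CCDC40 -0.052, CFAP43 -0.024 and CCNO -0.071; for the Stiiizy disposable, HSPH1 -0.027, CRELD2 -0.153, DNAI1 -0.011, DNAH11 -0.099 and PLK4 -0.013; for Strawberry juice, AKR1C2 0.003, CEBPG 0.114, PSAT1 0.006, DNAJB9 0.006, BNIP3 0.118, CDKN1A 0.131, CCNO 0.027, SCNN1A 0.104, NPAS2 0.036 and CRY1 0.076; and for distillates minus juices, HSPH1 -0.127, HSPB1 -0.087, MT1E -0.044, CCDC40 -0.035 and CFAP43 -0.013. None of these reversed changes passed an adjusted p of 0.05 with ERCC factors. How the spike-ins were added is not stated, and the cause was not tested.

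Counts were simulated for the Palmetto cartridge (21664 genes), with 50 genes changed per size and direction. The changed genes all had a mean of at least 1 CPM. Recovered were 100% of genes raised and 98% of genes lowered by 1 on the log2 scale, and 78% in each direction at 0.5. Of 21464 unchanged genes 10 were called. In the data 11706 genes were called for this product, so the simulation does not test the scaling under changes that wide.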

Other observations

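The list tests here were fixed before the data were examined, and the bounds for read-through and gene span were written before their values were seen. The restriction of gene span to protein-coding genes was not part of what was written. For circadian clock output, 3, 4, 4 and 3 of the 15 tested members rose and 9, 8, 10 and 11 fell, or 3, 4, 4 and 3 and 9, 9, 11 and 11 adjusted over the list alone. Its median log2 changes were -0.41, -0.27, -0.30 and -0.55. Camera called the Stiiizy disposable (adjusted p = 0.0012, 0.20 with an estimated correlation), with adjusted p = 0.083 to 0.20 in the others. Tested directly, the list was lower with the Stiiizy disposable than with the Not Ya Son's Weed cartridge (adjusted p = 1.8e-07, 0.020 with an estimated correlation) and the Palmetto disposable (1.3e-09, 0.020), and the difference from the Palmetto cartridge (0.00019, 0.14) was lost with that correlation. BHLHE40 rose by 1.92 ± 0.09 to 2.70 ± 0.09 and PER1 by 0.95 ± 0.10 to 1.61 ± 0.10, while TEF changed by -1.40 ± 0.08 to -0.92 ± 0.08. For glucocorticoid response, 6, 6, 6 and 5 of the 11 tested members rose and 3, 3, 3 and 2 fell, or 6, 6, 6 and 5 and 3, 3, 4 and 2 adjusted over the list alone. Medians on the log2 scale were 0.23, 0.38, 0.20 and 0.09, with camera adjusted p = 0.14 to 0.22, and FKBP5 changed by -1.20 ± 0.10 to -0.88 ± 0.10. For cannabinoid and TRP receptors, 3, 5, 5 and 5 of the 10 tested members rose and 2, 2, 3 and 1 fell, or 4, 5, 5 and 5 and 2, 2, 3 and 1 adjusted over the list alone. In the list the median log2 changes were 0.22, 0.15, 0.14 and 0.49, with camera adjusted p = 0.17 to 0.58. TRPV4 rose by 0.56 ± 0.06 to 0.77 ± 0.06 and FAAH by 0.70 ± 0.09 to 0.81 ± 0.09, and MGLL changed by -0.42 ± 0.07 to -0.32 ± 0.07. For xenobiotic and aldehyde metabolism, 4, 2, 3 and 3 of the 22 tested members rose and 8, 9, 8 and 8 fell, or 4, 2, 3 and 3 and 9, 9, 8 and 8 adjusted over the list alone. Median log2 changes were -0.15, -0.14, -0.16 and -0.05, with camera adjusted p = 0.076 to 0.25. For airway ion transport, 4, 3, 4 and 3 of the 17 tested members rose and 9, 10, 9 and 11 fell, or 4, 3, 4 and 3 and 10, 10, 9 and 11 adjusted over the list alone. The medians of log2 change were -0.25, -0.25, -0.20 and -0.22, with camera adjusted p = 0.066 to 0.20. For rare epithelial cell markers, 7, 6, 7 and 7 of the 14 tested members rose and 2, 2, 1 and 1 fell, or 7, 6, 7 and 8 and 2, 3, 1 and 1 adjusted over the list alone. Its median log2 changes were 0.52, 0.23, 0.37 and 0.68. The Stiiizy disposable passed (adjusted p = 0.039, 0.39 with an estimated correlation), against 0.13 to 0.45 in the others, but no difference passed in the list between it and the Palmetto cartridge (0.33) or the Palmetto disposable (0.11). The difference from the Not Ya Son's Weed cartridge passed (adjusted p = 0.0046, 0.32 with an estimated correlation). CFTR rose by 0.38 ± 0.08 to 1.20 ± 0.08.

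The median, the mean and the camera direction of a list differed in sign for heat shock proteins (Not Ya Son's Weed cartridge, Serene Tree Strawberry juice), ATF4 integrated stress response (Not Ya Son's Weed cartridge, Palmetto disposable, distillates against juices), AHR targets (distillates against juices). It was also so for interferon response (Stiiizy disposable, distillates against juices), PPAR and lipid handling (Palmetto cartridge, Not Ya Son's Weed cartridge, Palmetto disposable, Stiiizy disposable, Serene Tree Strawberry juice, distillates against juices), hypoxia response (Palmetto cartridge, Stiiizy disposable). It was also so for p53 targets (Serene Tree Strawberry juice), markers of non-epithelial cells (Palmetto cartridge), cannabinoid and TRP receptors (Serene Tree Strawberry juice). It was also so for airway ion transport (Serene Tree Strawberry juice, Serene Tree Green Apple juice), circadian clock output (Not Ya Son's Weed cartridge, Palmetto disposable, distillates against juices).

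Transcription past the ends of expressed genes was tested as a hypothesis for the higher number of detected genes with distillates. The 469 low-count genes within 10000 bases downstream, on the same strand, of a gene at 10 CPM or more had a median log2 change (distillates minus juices) of 0.625, and 267 genes lying upstream had 0.429. The difference was 0.196 (permutation p = 0.02, 100000 permutations, genes treated as independent), between the bounds set in advance, and 4017 genes elsewhere had a median of 0.394. The values do not decide whether read-through took part, and whether counting used strand is not stated. Gene span was tested as another trend, and the Spearman rho of log2 change with log10 span over 21390 genes was -0.128 to -0.207 in the 4 distillates. The bounds set in advance were beyond 0.2 in size in all 4 for an effect and within 0.1 in all 4 against it, and neither was met. Over protein-coding genes alone rho was -0.11 to 0.036, with both signs, which does not support an effect of span on genes in general.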
